A study of Mus musculus with 2 samples.

How the data were processed

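Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse embryonic fibroblasts (MEFs) that carried doxycycline-inducible, FLAG-tagged Myod1 and the transactivator rtTA. Per the labels' protocols, fibroblasts were isolated from embryos heterozygous for a Tau-EGFP knock-in, infected, and kept in doxycycline for 48 hours. The sample list holds 2 libraries of this 1 group, replicates 1 and 2. The labels do not say whether the replicates came from separate embryos or cultures, so the spread between them may be technical.

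The deposited table gives 26500 sites of 200 bp with RPKM values (reads scaled by site length and library size) that the authors quantile normalized, as the name of the deposited file states. Site names call the sites merged peaks of sets abbreviated A and M, and the file does not spell these out. The name of the site set also holds the label noAMcds, which is not explained. It may mean that sites in coding sequence of the A and M factors were left out. Sites counted at Ascl1 and Myod1 may then be incomplete. The submitters' processing notes name Bowtie2 2.1.0, Picard 1.79 and build mm10. The role of each tool, the aligner settings, the peak caller, the read shift for Tn5, the handling of duplicates and of reads with several matches, and the counting tool are not given in the sources used here. The values themselves were checked for the normalization. The sorted values of the libraries differed by a median of 0.42%, and 97.4% of the values were whole multiples of 0.01/6 within 0.0001 of a step, as a mean over 6 columns of 2-decimal values at each rank would be. Quantile normalization gives every library nearly the same distribution, so a value is in effect the rank of a site within its library, and no difference in total accessibility between libraries can be seen. It was done jointly with libraries that are not analysed here. No read counts were given, so the depth is unknown, and no counting interval, count test or floor was computed.

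Of the per-library columns in the table, 4 belong to libraries outside the sample list (fibroblasts alone, fibroblasts with rtTA, and Ascl1) and were not used in any step. Columns prefixed MD were read as Myod1 because no other labelled transgene fits that prefix. A comparison of Myod1 with control or Ascl1 cells was therefore not made, and with a single group there is no test between conditions. What follows describes the relative accessibility of sites within the Myod1 libraries.

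Values were put on a log2 scale with a pseudocount of 1. Fold differences on that scale understate the change of low sites. Sites were read as BED intervals and are given 1-based on mm10. Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 21900 protein-coding genes. That table has no strand, exons or UTRs, and no genome sequence was used here. Each site was therefore assigned to the protein-coding gene whose span contains its centre or lies nearest within 100 kb, and the distance to the nearest annotated gene end, either the start or the end of a transcript unit, replaced the planned distance to the transcription start. Site classes were gene ends (centre within 1 kb), gene bodies and sites outside genes, all by protein-coding genes alone. The planned search for 20 motifs, the exon, intron and UTR classes, and classes of sites labelled in the file could not be computed.

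Gene lists (11 lists, 308 genes) were fixed before the data were examined: skeletal muscle, neuronal, Notch and bHLH regulators, fibroblast and matrix, housekeeping, and as other cell types cardiac, neural progenitor and glia, hepatic, haematopoietic, endothelial and epithelial. All symbols matched the table, 4 of them as older names of genes already listed. For each list, the median log2 value of its sites was set against 10000 random site lists of the same size matched on gene end distance (up to 1 kb, up to 10 kb, farther). Differences from random are the list's median minus the median of the random lists, for each library or for the mean of both log2 values. A list was said to stand apart where its median fell outside the central 95% of the random lists in each library and in their mean. By chance about 0.55 of 11 lists would do so in any single library, if sites were independent. Sites are not replicates, so the percentiles describe these libraries and are not p-values. No random list was matched on the peak set, A or M, from which a site came. The procedure was tested on simulated data by shuffling values within distance classes over 24966 sites and shifting a list by 0.5 on the log2 scale. It found the shifted skeletal muscle list in 98.5% and the neuronal list in 98.0% of 200 simulations, but the cardiac list of 19 sites in 30.0% and the hepatic list of 4 sites in 7.0%. With no shift, skeletal muscle was called in 3.5% and neuronal in 1.5%. The shuffling broke any likeness between sites of the same gene, so these rates hold for independent sites only. Whether a gene has a site depends only on site coordinates, and so on how the merged peaks were chosen. The count itself uses no level from the Myod1 libraries, but whether these libraries helped to choose the peaks is not known. The share of list genes with a site was set against 10000 sets of random genes matched on gene length. This comparison, and that of the libraries near gene lists by their median difference per site, were chosen after the data were seen.

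Named sites and genes followed a rule fixed before the data were examined: the 10 highest sites that were in the top 1% of each library; the 6 highest sites, 1 per gene, of the skeletal muscle and neuronal lists and the 2 highest of every other list; the 3 sites that differed most between the libraries in each direction, among sites above the median; and the highest site of 13 fixed genes. Alternatives were pseudocounts of 0.1 and 5, leaving out the lowest 10% of sites, leaving out each replicate, gene distances of 20 and 10 kb, gene ends within 500 bp or 2 kb, the highest site per gene, no matching, and random lists of whole genes. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used.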

Results

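Accessibility was examined in fibroblasts 2 days after induction of Myod1, the basic helix-loop-helix (bHLH) factor that drives skeletal muscle identity. The study's design set these cells beside fibroblasts alone, fibroblasts with rtTA, and fibroblasts with Ascl1, a proneural bHLH factor. Only the 2 Myod1 libraries are analysed here, so the question that can be addressed is which of the 26500 sites, and which groups of genes, were more or less accessible within Myod1-expressing cells. The median site had 4.85 RPKM in replicate 1 and 4.84 RPKM in replicate 2, with an interquartile range of 2.86 to 8.51 RPKM in each. The highest value was 684.92 RPKM in both, as quantile normalization imposes.

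The libraries ranked the sites alike. Across sites, which are not independent replicates, Pearson's r of log2 values was 0.87 and Spearman's rho 0.85. Of the 2650 sites in the top 10% of replicate 1, 68.9% were in the top 10% of replicate 2, against 10% by chance. The per-site difference between libraries had an SD of 0.50 on the log2 scale, and 1183 sites (4.46%) differed by more than 2-fold. Over quintiles of mean level this spread was between 0.47 and 0.54, with the lowest value in the highest quintile.

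**Figure D1:**
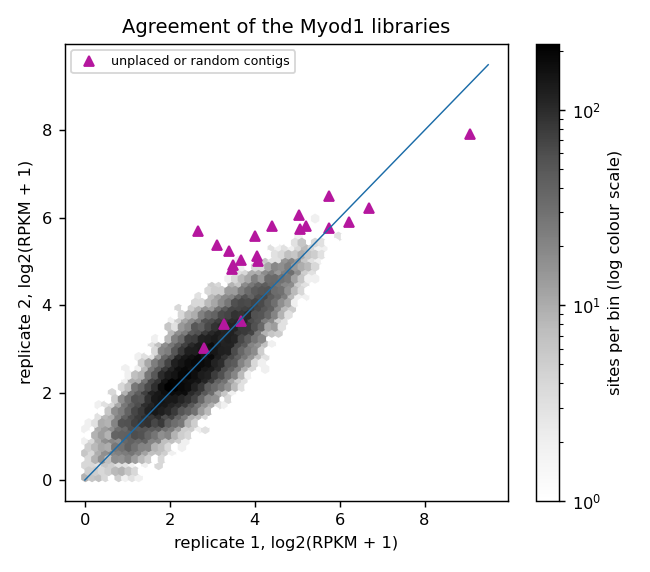
Each bin counts sites by their log2(RPKM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), with darker bins holding more sites on a log colour scale; the line marks equal values and triangles mark the 21 sites on unplaced or random contigs. Most sites lie along the line (Pearson's r 0.87), while the contig sites lie high and mostly above it, with a median difference of -0.94 for replicate 1 minus replicate 2.

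Among sites on assembled chromosomes, those at gene ends were the most accessible of the 3 classes. The 5202 sites within 1 kb of an annotated end of a protein-coding gene had a median of 6.15 RPKM in each library, the 13235 other sites in gene bodies 4.77 ± 0.06 RPKM (SD, n = 2), and the 8042 sites outside genes 4.30 ± 0.02 RPKM (SD, n = 2). On the log2 scale gene ends exceeded the other placed sites by 0.35 ± 0.003 (SD, n = 2) and gene bodies exceeded sites outside genes by 0.12 ± 0.01 (SD, n = 2), both larger than the spread between replicates. In libraries normalized to nearly the same distribution, medians over so many sites vary little, so this spread does not measure biological variation. Outside genes the median was 4.49 ± 0.10 RPKM up to 10 kb from a gene and 4.15 ± 0.08 RPKM beyond 100 kb (SD, n = 2). Either end of a gene could be its promoter, since strand was not known.

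Most skeletal muscle genes carried a site of the merged peaks, a count that uses no accessibility values beyond any used to choose the peaks. Of 62 list genes 48 (77.4%) had a site, where random genes of like length had one in 46.8% (central 95% 35.5% to 58.1%). The number of sites per gene, 1.53 against 1.08 at random, was within the range of random genes (percentile 95.2). Their 95 sites had a median log2 value of 2.90, 0.29 above matched random sites and at percentile 99.2 of the random lists. The libraries differed in this. In replicate 1 the median was 0.49 above random, at percentile 100, and in replicate 2 it was 0.14 above, at percentile 85.1, so the list did not stand apart in both libraries. Among the 63 muscle sites over 1 kb from any gene end, a subset chosen after the data were seen, the median was 0.46 above random in replicate 1 (percentile 99.7) and 0.37 above in replicate 2 (percentile 99.2), while the mean of the libraries, at percentile 97.4, stayed just inside the central 95%. In both libraries 50 of the 95 sites (52.6%) lay above the median of all sites and 24 (25.3%) below it, compared with 41.0% and 41.5% of all sites.

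By mean log2 value, the highest muscle site lay 4.69 kb from Actc1, which encodes cardiac alpha-actin and is also used in developing skeletal muscle (chromosome 2, 114057470 to 114057669), with 19.9 ± 1.7 RPKM (SD, n = 2). A site inside Myl4, an embryonic myosin light chain gene (chromosome 11, 104576727 to 104576926), had 20.1 ± 6.2 RPKM. Sites inside Myom1, a sarcomere M-band gene (chromosome 17, 71038891 to 71039090), and 1.77 kb from Itga7, a laminin receptor of muscle (chromosome 10, 128931555 to 128931754), had 17.5 ± 0.10 and 17.4 ± 0.64 RPKM. The embryonic myosin heavy chain gene Myh3 had a site 3.59 kb away with 15.9 ± 1.1 RPKM, and Myom2 a site 8.01 kb away with 16.0 ± 5.9 RPKM. Each of these 6 sites was above percentile 85 of all sites in both libraries, but they were picked as the highest of the list. The top 10% of both libraries held 6 of the 95 muscle sites, compared with 1817 of all 26500 sites (6.86%). Muscle sites were thus not clearly more frequent at the very top.

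Other muscle genes fixed in advance had intermediate sites. The site at Ckm, muscle creatine kinase (chromosome 7, 19421354 to 19421553, 130 bp from a gene end), had 9.66 ± 2.05 RPKM (SD, n = 2). The highest Acta1 site, 6.88 kb from this skeletal alpha-actin gene, had 10.7 ± 3.2 RPKM, and the highest of 3 Myod1 sites, 26.2 kb from the gene (chromosome 7, 46350199 to 46350398), had 9.77 ± 1.88 RPKM. Sites in the coding sequence of Myod1 may have been left out of the set. The highest site near Myog, myogenin, 13.7 kb away (chromosome 1, 134276197 to 134276396), had 9.20 RPKM in replicate 1 and 4.53 RPKM in replicate 2, which places it above the median of all sites in the former and slightly below it in the latter.

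Neuronal genes had the opposite placement. Their 99 sites, near 36 of 54 list genes, had a median log2 value of 2.19, a difference of -0.35 from matched random sites, at percentile 0.08. The difference was -0.40 in replicate 1 (percentile 0.04) and -0.50 in replicate 2 (percentile 0), so it stood apart in both libraries. Against random lists of whole genes the neuronal list also stood apart (percentiles 0.14 and 0 in replicates 1 and 2). Whether sites near neuronal genes ranked low because of the peak set, A or M, that they came from was not tested. In both libraries 55 of the 99 sites (55.6%) were below the median of all sites and 27 (27.3%) above it. The share of neuronal genes with a site, 66.7%, was within the range of random genes of like length (46.3% to 70.4%). Without matching on length that share was above the random range (percentile 99.75). With the lowest 10% of all sites left out, a filter on the same values that are compared, the 77 neuronal sites had a difference of -0.21, at percentile 9.16 in replicate 1 and 0.84 in replicate 2, and the list no longer stood apart.

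Some neuronal genes nevertheless had accessible sites. The highest lay 98.3 kb from Sox11, a transcription factor of immature neurons (chromosome 12, 27235842 to 27236041), with 23.3 ± 1.9 RPKM (SD, n = 2). A site inside Mapt, the tau gene, had 17.2 ± 3.6 RPKM. By its name, the Tau-EGFP knock-in of these cells lies in Mapt, and its effect on this site was not tested. A site 11.5 kb from the synapsin gene Syn2 had 15.6 ± 1.8 RPKM. A site inside Myt1l, a zinc finger factor used in neuronal reprogramming (chromosome 12, 29695369 to 29695568), had 15.4 ± 0.28 RPKM. Zbtb18 (also known as Zfp238), with a site 702 bp from the gene, had 14.1 ± 1.9 RPKM, and a site inside Nrxn3 had 12.8 ± 3.7 RPKM. The only site assigned to Ascl1 (chromosome 10, 87494793 to 87494992, 1.23 kb from the gene) had 1.38 ± 0.39 RPKM, at percentile 9.99 in replicate 1 and 4.69 in replicate 2. Sites in the coding sequence of Ascl1 may have been left out of the set. Insm1, Tubb3 and Cdkn1c had no site that was nearest to them within 100 kb.

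Genes of Notch signalling and bHLH regulation carried many sites of the merged peaks per gene, at levels within the range of random sites. Of 30 genes 26 (86.7%) had a site, against 43.3% of random genes of like length (central 95% 26.7% to 60%), with 3.33 sites per gene against 1 at random. Random genes were not matched on the distance to neighbouring genes, which also affects how many sites a gene collects. Within 20 kb these genes had 73 sites, and 83.3% of them had a site against 40% at random. The number of sites per gene was not compared with random at that distance. The median of the 100 sites differed from random by -0.17 in replicate 1 (percentile 7.57) and -0.11 in replicate 2 (percentile 18.1), and the list did not stand apart. A site 93.3 kb from Id2 and a site in Notch2 were highest, with 17.7 ± 2.2 and 16.8 ± 0.40 RPKM (SD, n = 2). Hes6, a bHLH gene shared by neurogenesis and myogenesis, had a site 664 bp from a gene end (chromosome 1, 91413275 to 91413474) with 16.2 ± 4.7 RPKM, and Id3, an inhibitor of bHLH factors, a site with 9.76 ± 1.58 RPKM. Of the Notch ligand genes named in advance, the highest of 7 Dll1 sites, 41.3 kb from the gene, had 5.48 ± 0.94 RPKM. The Dll3 site (chromosome 7, 28302246 to 28302445) had 1.64 ± 0.47 RPKM.

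**Figure D2:**
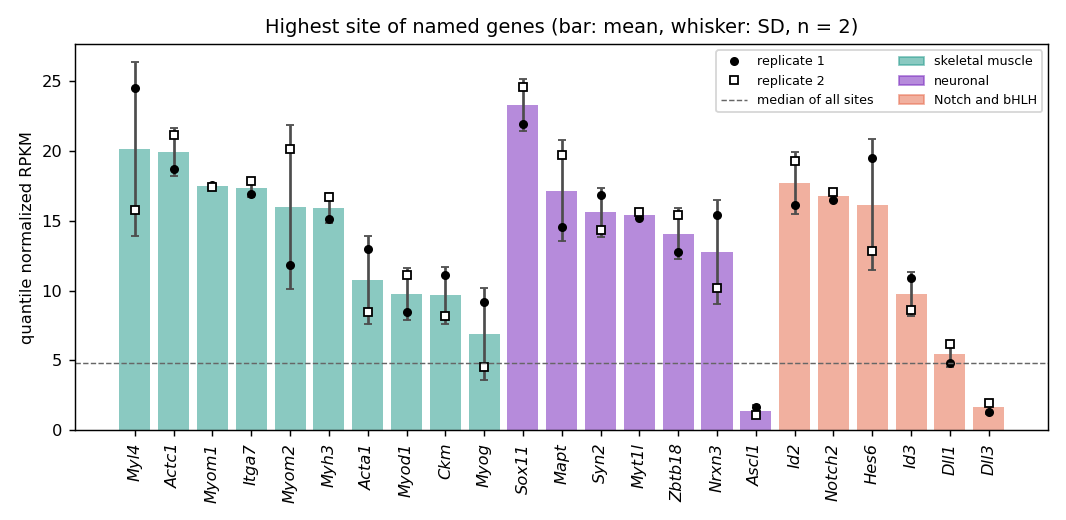
Bars give the mean quantile normalized RPKM (vertical axis, linear) of the highest site of each named skeletal muscle, neuronal and Notch or bHLH gene, whiskers the SD of the 2 libraries, and symbols the libraries; the dashed line is the median of all sites. Sites of Ascl1 (1.38 RPKM) and Dll3 (1.64 RPKM) lie below the median, while those of Sox11 (23.3 RPKM) and Myl4 (20.1 RPKM) are among the highest.

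Fibroblast and matrix genes were also rich in sites of the merged peaks, at levels like those of random sites. Of 43 genes 35 (81.4%) had a site, against 53.5% of random genes of like length, and their 142 sites had a median 0.10 above random for the mean of the libraries (percentile 83.4), with a difference of 0 in replicate 1 (percentile 49.96) and 0.04 in replicate 2 (percentile 64.3). The highest were 89.4 kb from Postn, periostin, with 32.9 ± 1.6 RPKM, and at the end of Acta2, smooth muscle actin (chromosome 19, 34255490 to 34255689), with 31.9 ± 2.5 RPKM (SD, n = 2). Housekeeping genes likewise had a site more often than random genes of like length, in 18 of 25 genes (72%) against 44% (central 95% 24% to 60%). Their 36 sites were 0.30 above random, with 0.47 in replicate 1 (percentile 98.6) and 0.18 in replicate 2 (percentile 82.1), and did not stand apart in both. The highest lay 11.4 kb from Emc7 (22.3 ± 3.1 RPKM) and 119 bp from Rplp0 (21.5 ± 5.4 RPKM).

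Among lists of other cell types, the 19 sites of cardiac genes differed from random by -0.56, at percentile 1.53 in replicate 1 and 0.07 in replicate 2, and stood apart. Without the lowest 10% of all sites, a filter on the compared values, the difference was 0.20 for the mean of the libraries, -0.15 in replicate 1 (percentile 28.6) and 0.08 in replicate 2 (percentile 61.7). With gene distances of 20 and 10 kb it stayed at -0.58 and -0.59, but replicate 2 was then within the range of random lists (percentiles 16.4 and 16.8). The highest cardiac sites were near Myl7 (13.1 ± 4.2 RPKM) and Myl3 (10.2 ± 1.7 RPKM). Neural progenitor and glial sites (24 sites) differed from random by -0.49 in replicate 1 (percentile 1.41) and -0.21 in replicate 2 (percentile 17.8). The highest of them was 2.03 kb from Nes (15.3 ± 5.3 RPKM) and the next 64.9 kb from Slc1a3 (8.52 ± 3.17 RPKM). Haematopoietic (10 sites, percentiles 3.40 and 8.96 in replicates 1 and 2), endothelial (15 sites, percentile 38.0), hepatic (4 sites, percentile 45.5) and epithelial (7 sites, percentile 71.7) lists did not stand apart, and the hepatic and epithelial differences had opposite signs in the libraries. Their highest sites were in Tek (22.3 ± 4.0 RPKM), 12.3 kb from Cldn4 (22.4 ± 2.8 RPKM), 78.2 kb from Cdh5 (14.3 ± 4.5 RPKM) and in Cdh1 (8.93 ± 1.61 RPKM). The others were in Itgam (7.65 ± 0.60 RPKM), 94.8 kb from Apob (6.99 ± 4.09 RPKM), in Hnf1a (5.05 ± 2.31 RPKM) and 6.37 kb from Laptm5 (4.61 ± 0.99 RPKM, SD, n = 2 throughout).

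**Figure D3:**
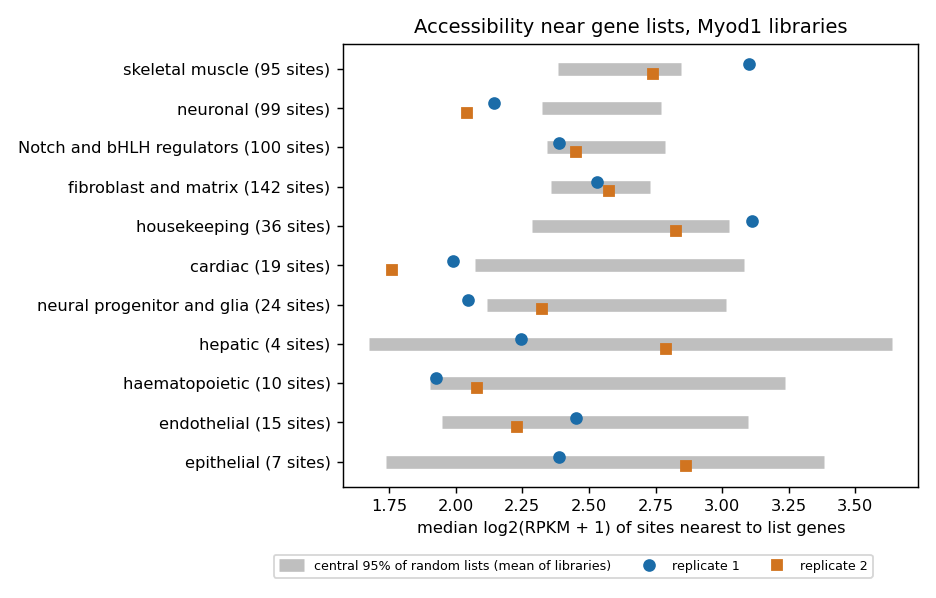
The horizontal axis is the median log2(RPKM + 1) of the sites nearest to the genes of each list, with circles for replicate 1 and squares for replicate 2; grey bars span the central 95% of 10000 random site lists matched on gene end distance, for the mean of both libraries. Neuronal sites lie below the bar in both libraries (percentiles 0.04 and 0), and skeletal muscle sites lie above it in replicate 1 (percentile 100) but not in replicate 2 (percentile 85.1).

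Sites near muscle genes were higher in replicate 1 than in replicate 2. The median per-site difference was 0.22 on the log2 scale, at percentile 100 of the random lists, and 59 of 95 sites were higher in replicate 1. Random lists of whole genes were not run for differences between libraries, so likeness between sites of the same gene was not allowed for. Housekeeping sites showed a median difference of 0.39 (percentile 99.98, 28 of 36 sites). Over 1 kb from gene ends this difference was 0.25 for 20 housekeeping sites, within the random range (percentile 97.15). The neuronal (0.09, percentile 92.6) and fibroblast (0.06, percentile 90.6) lists were within the range of random lists. The 4 hepatic sites differed in the other direction, by a median of -0.95 (percentile 0.03). Among single sites above the median, those most in excess in replicate 1 were in Rapgef1 (11.4 against 2.06 RPKM), 528 kb from Nectin3 (11.6 against 2.22 RPKM) and in Rd3 (13.7 against 3.12 RPKM). Those most in excess in replicate 2 were on the unplaced contig JH584304 at bases 73112 to 73311 (5.31 in replicate 1 against 50.7 RPKM) and 106734 to 106933 (7.69 against 40.4 RPKM), and on chromosome 9 at 3022077 to 3022276 (10.7 against 57.0 RPKM).

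Of the 10 highest sites, 8 lay on assembled chromosomes outside protein-coding genes. The highest 3 on chromosome 2 were within 98662637 to 98667144, over 1031 kb from Lrrc4c, the nearest protein-coding gene, with 684.92 RPKM in both libraries, 421 ± 168 and 260 ± 26 RPKM (SD, n = 2). The pair on chromosome 17, at 39844285 to 39844484 and 39847751 to 39847950, had 378 RPKM in both libraries and 357 ± 77 RPKM, the latter inside Rn18s-rs5, annotated as a ribosomal RNA pseudogene. A site on the unplaced contig JH584304 had 391 ± 211 RPKM, and a site on chromosome 9 (35305252 to 35305451), inside the long noncoding RNA gene Gm33838, 345 ± 93 RPKM. Sites on chromosome 3 (5860579 to 5860778) and chromosome 11 (109011801 to 109012000, inside the long noncoding RNA gene Gm36876) had 181 and 166 RPKM in both libraries. The last of these, on chromosome 16 (57391499 to 57391698), lay inside the overlapping genes Cmss1 and Filip1l with 145 ± 6.8 RPKM.

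Chromosomes differed little in level and more in the number of sites. Median log2 values of the 19 autosomes ranged from 2.45 to 2.62. The X chromosome held 206 sites, 21.3 per 100 protein-coding genes, against 127 on the autosomes together and 89.2 to 169 on single autosomes. Its median log2 value minus that of the autosomes was -0.23 in replicate 1 and -0.12 in replicate 2. No site was on the Y chromosome.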

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

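No paired analysis was possible because the replicate numbers belong to a single group. No result could be checked against another library type, and the depth, which is unknown, sets no usable limit. The directions of the skeletal muscle and neuronal lists held under every alternative run. Of 132 alternative values of the 11 lists, 117 were counted as keeping their direction and whether the list stood apart. That count includes the fibroblast and matrix list without replicate 2, whose difference of 0 has no direction. The alternatives that use the nearest gene end, only sites over 1 kb from a gene end, leave out sites over 100 RPKM or match on level, and all those for the share of genes with a site and for the difference between libraries, were chosen after seeing the data. The cause of the changes below was not tested, except that pseudocounts rescale every log2 value by construction, and that the filter on low sites acts on the compared values. A pseudocount of 0.1 moved the median log2 level to 2.31, the excess of gene ends to 0.41, that of gene bodies to 0.15 and the SD between libraries to 0.64; a pseudocount of 5 moved them to 3.30, 0.21, 0.071 and 0.30, and the X minus autosome difference to -0.10. Without the lowest 10% of sites these were 2.68 for the level, 0.26 for gene ends and 0.074 for gene bodies, Pearson's r was 0.83 and Spearman's rho 0.81, the neuronal difference of -0.21 no longer stood apart and the cardiac one turned to 0.20 for the mean of the libraries. With gene ends taken within 500 bp the excess was 0.44 for gene ends and 0.11 for gene bodies, and within 2 kb it was 0.27 for gene ends. Leaving out a replicate gave 0.14 to 0.49 for skeletal muscle and 0.18 to 0.47 for housekeeping, and -0.49 to -0.21 for neural progenitors, each apart from random in replicate 1 alone. It gave -0.35 to 0.20 for hepatic and -0.11 to 0.37 for epithelial sites. With genes within 20 kb, cardiac sites were at -0.58 and epithelial sites at -0.11, and within 10 kb at -0.59 and -0.44. With the highest site per gene, Notch and bHLH genes were at 0.0062, cardiac at -0.93 and epithelial at -0.0047. The cardiac list stood apart in none of these 3 settings. Only sites over 1 kb from a gene end gave 0.029 for hepatic sites, and 0.25 for the housekeeping difference between libraries, which was then within the random range. For the share of genes with a site, no length matching put neuronal genes 20.4 percentage points above random (percentile 99.75), outside the random range. Genes within 20 kb put hepatic genes at -31.2 points (percentile 0.725), also outside it, and neural progenitors at -5 points. The motif, exon and labelled-class results were not run.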

Other observations

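Beyond the fixed lists, gene families were taken by the stem of their symbols, a choice made after the data were seen. Of 120 stems with at least 20 sites and 8 genes, 4 stood above and 5 below matched random sites in both libraries. Chance would give about 6 in any single library if sites were independent, and at most that many in both. Sites of a stem often share a gene, which can raise that number, and random lists of whole genes were not run for stems. Which of the stems that stood apart exceed chance therefore cannot be told from this count. Sites of unconventional myosin genes (Myo, 71 sites, 17 genes) were 0.49 above random in replicate 1 and 0.42 in replicate 2. The differences were 0.57 and 0.54 for Klhl genes, 0.48 and 0.36 for tetraspanins (Tspan) and 0.45 and 0.40 for Inpp phosphatases. Below random were sites of voltage-gated calcium channel genes (Cacna, 52 sites) with differences of -0.52 and -0.46, of synaptotagmins (Syt) with -0.75 and -0.66, of Bmp genes with -0.46 and -0.73 and of Unc genes with -0.49 and -0.57, and of the Krtap genes described further on. Gse1 held the most sites, 67 assigned to a gene of 353 kb, with a median of 5.76 RPKM, followed by Zmiz1 with 42 sites (median 5.71 RPKM) and Tspear with 34 (median 1.62 RPKM).

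The tests of muscle sites away from gene ends, of matching on level, of ribosomal and similar genes, of contig sites and of Krtap copies were chosen after the results they bear on were seen. For sites around the Krtap clusters the prediction was written before that test was run. The Krtap pattern itself came from the families, a choice made after the data were seen. No biological explanation from the design was tested, since both libraries belong to the same group.

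Muscle-list sites were higher in replicate 1 by a median of 0.22. More signal at gene ends as the whole cause is argued against by the 63 muscle sites over 1 kb from any gene end, whose median difference of 0.20 was at percentile 99.65. That percentile takes sites of the same gene as independent. Random lists matched on level left the muscle list at percentile 99.97, but this decides nothing, since in these quantile normalized values the median difference was within 0.03 of 0 at every decile of level. Sites of the housekeeping list differed in the same direction, within the random range over 1 kb from gene ends (0.25, percentile 97.15), but 200 sites of Rpl, Rps, Eif, Psm and Nduf genes had a median difference of -0.0087 (percentile 39.8), which argues against more signal near every widely used gene. Uneven induction of Myod1 or unequal numbers of infected cells, if the replicates were separate cultures, may contribute and stays open as an untested hypothesis. The median difference of all 36 housekeeping sites, 0.39, was larger than that of muscle sites, so the difference was not particular to muscle genes.

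Most of the 10 highest sites lay outside protein-coding genes. Of the 20 highest, 2 (10%) were within 1 kb of an end of such a gene, against 109 of the following 245 sites (44.5%). Among all sites the share was 19.6%, so the contrast is mainly with the sites that follow. Sites away from gene ends can still lie inside a gene, so this count covers gene ends only. Reads from multi-copy sequence, gathered on few reference copies, are a candidate explanation: the 21 sites on unplaced or random contigs had a median level at percentile 96.0, and 14 were in the top 10%. Without sequence or mappability, this remains an untested hypothesis for the highest sites.

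Sites in clusters of Krtap genes, which encode keratin-associated proteins of hair, were at very low levels. The cluster on chromosome 11 (99580779 to 99993984) held 51 sites with a median of 0.87 RPKM, that on chromosome 7 (142174851 to 142304245) 13 sites with 0.79 RPKM, and the Tspear region on chromosome 10 (77666533 to 77862726) 34 sites with 1.62 RPKM. Sites assigned to Krtap genes differed from random by -1.96 in replicate 1 and -1.60 in replicate 2. A wider domain of low accessibility is argued against by 71 sites within 500 kb of the clusters, which had a median of 5.26 RPKM at percentile 65.5. Loss of reads shared between near-identical gene copies may explain the 0.93 RPKM median of 38 Krtap sites, but cannot be told apart from low accessibility of these sites, because neither read data nor sequence was used here.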
